A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

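The set held 15 2-colour DNA microarrays of Saccharomyces cerevisiae cells of the W303 background and mating type a, each comparing RNA from treated cells with RNA from cells in mid-log growth, except for 1 array that compared an snf1 deletion strain with the wild type, both in mid-log growth. Treatments lasted 20 minutes. Every condition had 1 array, so there were no replicates, and the number of arrays limits the precision of every value. A second mutant strain was not analysed here. The values deposited by the authors were log ratios of Cy5 over Cy3 rounded to 2 decimals. Their base is not given in the sources used here, and log2 was taken for the deposited values because the extremes, −7.18 and 9.47, would be beyond the range of a scanner on a log10 scale. A base other than 2 would rescale every value and every count of 2-fold changes. Background correction, normalisation and spot filtering are not given in the sources used here. The number of columns left unused was 0.

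Per the labels, treated cells were in Cy5 on the other arrays and in Cy3 on the oxidative stress array. That array was turned so that a positive value means higher in treated cells throughout. As deposited it had Pearson correlations across gene probes of −0.671 to −0.381 with the other arrays, leaving aside the mid-log strain array. Once turned, it had 0.501 to 0.651 with the other 6 wild-type arrays of single treatments, over genes with a value on every array. On 6 arrays (rapamycin, nitrogen starvation, amino acid starvation, osmotic stress, heat shock and the mid-log strain comparison) between 717 and 1256 spots were exactly 0, against 21 to 48 on the 8 arrays that kept a ratio for dim spots, and the oxidative stress array had blanks for dim spots. The zeros on those 6 arrays were treated as no value, a choice made after seeing the data. The list tests, the gene lists, the ratio directions, the models, the thresholds and the rule for naming genes were chosen before the data were examined.

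The table had 6256 gene probes and 61 control spots. A gene symbol was given for 4075 probes, several symbols for 0 probes and none for 2181 probes. Symbols were brought up to date for 129 probes, and 4071 symbols matched the annotation of the reference genome. Probes without a symbol were kept in the tests and counts under their own identifiers but could not be named or placed in a list. Replicate probes were averaged for 7 genes, which left 6249 genes or probes, of which 4068 had a name. The 4653 genes with a value on all 15 arrays, 3355 of them named, were used throughout, and 1596 were left out. Near-identical genes, such as HXT6 and HXT7, the A and B copies of ribosomal protein genes, CUP1-1 and CUP1-2, and the alpha genes at HML and MAT, can share signal, so which copy a value belongs to is uncertain. Medians of all genes were within 0.1 of 0 except at −0.12 for wild-type cells in 0.1% glucose, −0.12 for snf1 cells in 0.1% glucose, −0.22 for nitrogen and glucose starvation and −0.19 for glucose starvation with rapamycin. Values were not recentred.

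Single arrays and 14 differences between arrays were described by the number of genes at least 2-fold higher or lower (an absolute log2 value of at least 1) and by medians of gene lists, without p values. List medians carry 95% bootstrap intervals over the members (2000 draws), which cover the spread between genes and not that between cultures, and a percentile among 10000 random lists of the same size. Of 26 fixed lists 24 were tested: cytosolic ribosomal proteins, mitochondrial ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, translation factors, amino acid biosynthesis, the sulfur amino acid pathway, nitrogen catabolite repressed genes, the retrograde response, the general stress response, heat shock factor targets, oxidative stress defence, the osmotic stress response, glucose-repressed genes, respiration and the TCA cycle, glycolysis, autophagy, the proteasome, purine synthesis, G1 cyclins and G1/S genes, histones, ergosterol synthesis, a-specific genes and the haploid pheromone pathway. The alpha-specific and the meiosis lists each had 1 member with a value on every array, fewer than the 3 needed, and were not tested.

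Tests were made with 3 limma models (limma 3.58.1 in R 4.3.3) with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The common response was the mean of the 7 wild-type arrays of single treatments against 0. Starvation was compared with stress as 3 arrays (nitrogen, amino acid and glucose) against 3 arrays (osmotic, heat and oxidative), leaving rapamycin out. The response of snf1 cells was compared with that of wild-type cells over 6 arrays, with the treatment as a block. The spread in these models is that between treatments, and the mid-log control enters each ratio. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists, and for the common response by an exact two-sided sign-flip test of the list median, whose smallest possible p is 0.0156 over 128 sign patterns. The models were tested on simulated data with 100 genes changed by a log2 value of 1 and 100 by 2.

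Genes named in the text came from a fixed rule: a set of 47 index genes, the 8 highest and 8 lowest named genes of each array and each difference, the 10 largest positive and 10 largest negative coefficients among the genes called in a model or the 5 with the smallest p where none were called, and for each list the 3 members farthest in the direction of the list median and the 1 farthest in the other direction. SNF1 was reported for every array, and had no value on the mid-log strain array. Alternatives tried were centring each array on its median, all genes with a value, the oxidative stress array as deposited, the probe with the largest ratio in place of the mean, scaling arrays to 1 spread, robust limma, leaving out each array, a looser filter on missing values, rapamycin among the starvations, no treatment block, an estimated correlation and members found in 1 list only. Zeros kept as values, the arrays with filled zeros alone and all list members with a value were added after seeing the data. Other computing used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.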

Results

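Gene expression was measured in wild-type and snf1 yeast cells taken from mid-log growth and exposed for 20 minutes to starvation, stress or rapamycin, an inhibitor of the TORC1 kinase complex that couples growth to nutrients. Snf1 is the yeast AMP-activated protein kinase, needed for growth on carbon sources other than glucose. Of the 15 arrays, 7 held wild-type cells under a single treatment (200 nM rapamycin, nitrogen starvation, amino acid starvation, 0.1% glucose, 0.375 M KCl, heat shock at 42 °C and 0.4 mM hydrogen peroxide) and 3 held wild-type cells under combined treatments. A further 4 held snf1 cells (nitrogen starvation, 0.375 M KCl, 0.1% glucose and 0.02% glucose), and 1 compared snf1 with wild-type cells in mid-log growth. Values are log2 ratios of treated over mid-log cells, 1 array per condition, over 4653 genes.

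SNF1 itself could not be used to check the deletion, because it had no value on the mid-log strain array, where it was listed at 0. On the wild-type arrays it was at −0.25 with rapamycin, −0.06 in nitrogen starvation, 0.11 in amino acid starvation, 0.64 in 0.1% glucose, 0.36 in KCl, −0.26 at heat shock and 0.36 in peroxide. In combined treatments it was at 0.45 in nitrogen and glucose starvation, 0.45 in glucose starvation with rapamycin and 0.20 in nitrogen starvation with KCl. In the snf1 strain the ratio was 0.32 in nitrogen starvation, 0.05 in KCl, 0.95 in 0.02% glucose and 2.57 in 0.1% glucose. Both channels would hold background in this strain if the probe lies in the deleted part. The ratio was within the range of blank control spots in KCl (−1.48 to 3.91) and 0.1% glucose (1.03 to 3.22). It was above that range in nitrogen starvation (−2.71 to 0.10) and 0.02% glucose (−2.03 to 0.35).

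The first comparison asked which genes moved the same way under all 7 single treatments of wild-type cells. Genes for making ribosomes fell and genes of the general stress response rose. Of 64 ribosome biogenesis genes, which act in the nucleolus on ribosomal RNA and preribosomes, 63 fell (63 adjusted over the list alone) with a median coefficient of −2.31, and SPB1 alone did not pass at 0.38. Of 45 general stress genes, targets of the Msn2 and Msn4 activators, 44 rose (45 adjusted over the list alone) with a median of 2.61, and GLG2 missed the threshold at 0.54. In all, limma called 1065 genes higher and 1312 lower.

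The largest falls included genes of ribosome synthesis. URA7, a CTP synthase, fell with a coefficient of −3.65 (SE 0.289, adjusted p = 5.69e-05), and NSR1, a nucleolin-like protein, with −3.44 (SE 0.301, adjusted p = 7.35e-05), both below 0 on 7 of 7 arrays. The rRNA processing factors RRP12 (−3.14) and UTP20 (−3.01), the fibrillarin gene NOP1 (−3.05), the rRNA acetyltransferase gene KRE33 (−2.95) and the 60S export factor gene ARX1 (−2.95) fell with them. So did AAH1, an adenine deaminase (−3.04), IMD4, an IMP dehydrogenase (−2.99), and ZRT1, the high-affinity zinc transporter (−3.08), each below 0 on 7 of 7 arrays. The largest rises were in DDR2, a multistress response gene (5.56, SE 0.396, adjusted p = 5.69e-05), and SPI1, a cell wall protein gene (4.45, SE 0.638, adjusted p = 0.000496). They were followed by the membrane heat shock gene HSP30 (4.12), the carbonic anhydrase gene NCE103 (3.74), PHM7 (3.72), the hexose transporter gene HXT5 (3.67), MSC1 (3.60), the transketolase gene TKL2 (3.57), ATO2 (3.39) and the aldehyde dehydrogenase gene ALD3 (3.38), all above 0 on 7 of 7 arrays.

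Other growth lists fell too. Of 135 cytosolic ribosomal protein genes 121 fell and 1, RPL15B, rose (0.61), with a median of −1.42 (123 lower and 1 higher adjusted over the list alone). All 14 genes of RNA polymerases I and III fell (14 adjusted over the list alone, median −1.74), as did 26 of 30 translation factor genes (27 adjusted over the list alone, median −1.22) and 14 of 17 G1 cyclin and G1/S genes (15 adjusted over the list alone, median −0.79), among them the G1 cyclin gene CLN2 (−1.82), RNR1 of ribonucleotide reductase (−1.95) and the DNA polymerase gene POL1 (−1.87). By camera at the preset correlation adjusted p was 1.03e-23 for ribosome biogenesis, 1.97e-20 for ribosomal proteins, 1.06e-07 for the polymerases, 3.54e-09 for translation factors and 5.08e-04 for the G1/S genes. With an estimated correlation adjusted p was 0.262, 0.387, 0.262, 0.267 and 0.387, so none of these list calls held by that test. The exact two-sided sign-flip test gave p = 0.0156, the smallest it can give, for each of these 5 lists (adjusted p = 0.0312). That test treats the arrays as independent, which they would not be with a shared mid-log control.

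Among rising lists, the general stress genes had an adjusted p of 2.39e-17 by camera and 0.312 with an estimated correlation. Of 32 glucose-repressed genes, for using other sugars and scavenging glucose, 22 rose (23 adjusted over the list alone, median 1.55), and of 28 genes repressed by good nitrogen sources 16 rose (17 adjusted over the list alone, median 1.49). Of 20 osmotic stress genes 13 rose (13 adjusted over the list alone, median 1.30), and of 15 autophagy genes 11 rose (11 adjusted over the list alone, median 0.87), led by ATG8 (2.43), the ubiquitin-like protein of the autophagosome membrane. Of 32 oxidative defence genes 18 rose and 2, TKL1 (−1.25) and YCF1 (−0.38), fell (19 and 3 adjusted over the list alone, median 0.63). Of 43 genes of respiration and the TCA cycle 11 rose and 1 fell (5 and 0 adjusted over the list alone, median 0.37), the citrate synthase gene CIT1 by most (1.59), and of 32 proteasome genes 4 rose (0 adjusted over the list alone, median 0.27). Camera gave adjusted p of 1.06e-07, 9.48e-06, 1.47e-04, 9.48e-06, 1.43e-04, 1.26e-03 and 8.23e-03 in that order. With an estimated correlation adjusted p was 0.387, 0.504, 0.402, 0.262, 0.262, 0.686 and 0.686. The sign-flip adjusted p was 0.0312 for the first 5 of these lists, for the general stress genes and for the haploid pheromone pathway.

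The remaining lists did not pass camera. Of 53 amino acid biosynthesis genes 14 fell and 1, LYS1, rose (9 and 1 adjusted over the list alone, median −0.40, camera adjusted p = 0.0748), with PRO1 of proline synthesis lowest at −1.84. Of 22 ergosterol genes 9 fell and 1 rose (9 and 1 adjusted over the list alone, median −0.24, adjusted p = 0.0687), ERG3 to −1.46. Of 28 heat shock factor targets 10 rose and 2 fell (10 and 1 adjusted over the list alone, median 0.39, adjusted p = 0.0687). Of 8 genes of the haploid pheromone pathway 4 fell (4 adjusted over the list alone, median −0.46, adjusted p = 0.0687), with FAR1 at −1.45, and of 10 histone genes 3 fell (3 adjusted over the list alone, median −0.27, adjusted p = 0.29). Of 16 purine synthesis genes 5 fell (5 adjusted over the list alone, median −0.03, adjusted p = 0.394), and of 7 retrograde genes, which respond to mitochondrial state, 3 rose (3 adjusted over the list alone, median 0.59, adjusted p = 0.157). Glycolysis had 2 higher and 3 lower of 20 (2 and 3 adjusted over the list alone, adjusted p = 0.838), with a median just below 0 at −0.02 and a mean above it at 0.09. Of 33 mitochondrial ribosomal protein genes 2 fell (0 adjusted over the list alone, median −0.10, adjusted p = 0.63). The 19 sulfur amino acid genes gave 0 calls in limma (0 adjusted over the list alone, median 0.37, adjusted p = 0.312), and 3 of 6 a-specific genes rose and 1 fell (3 and 2 adjusted over the list alone, median 0.17, adjusted p = 0.555).

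By size, 95 genes were at least 2-fold higher and 133 at least 2-fold lower on all 7 arrays, where independent arrays would give 0.00234 and 0.00888. The lower set held 48 ribosome biogenesis, 15 ribosomal protein and 8 polymerase genes, and the higher set 19 general stress, 4 glucose-repressed, 3 osmotic stress, 3 oxidative defence and 2 heat shock factor genes, ATG8, and 3 nitrogen-repressed genes (APE1, PUT1 and PUT4), some of them on several lists. Pairs of the 7 arrays had Pearson correlations across genes of 0.501 to 0.885, highest for nitrogen with amino acid starvation, followed by 0.838 for glucose limitation with KCl. Genes are not independent replicates, and unchanged arrays sharing 1 control pool would give 0.502 in simulation, so part of the excess may come from a shared control.

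**Figure D1:**
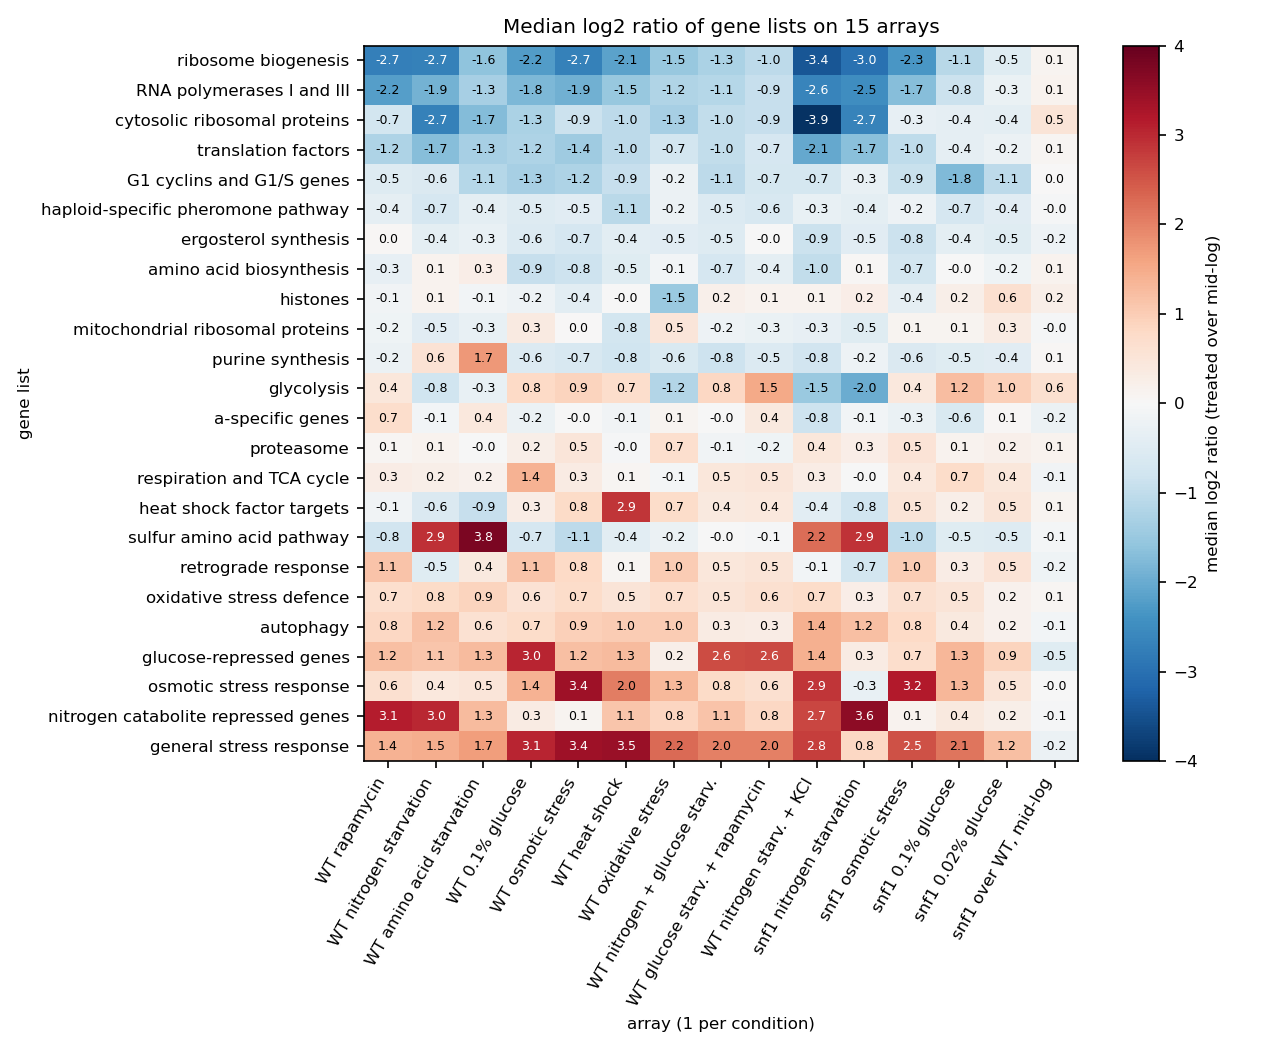
Median log2 ratio of treated over mid-log cells for gene lists (vertical) on each array (horizontal), as coloured cells. Ribosome biogenesis ran from −2.73 with rapamycin to −1.52 in peroxide on the 7 single treatments of wild-type cells, and the general stress list from 1.39 to 3.45.

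Each single treatment also had its own genes, described here without a test. Rapamycin (484 genes at least 2-fold higher, 562 lower) and nitrogen starvation (636 higher, 742 lower) shared high values of the nitrogen catabolite repressed genes, for uptake and breakdown of poor nitrogen sources, with list medians of 3.15 [95% interval 2.38 to 4.48] and 3.01 [2.30 to 4.49]. DAL5, an allantoate permease, stood at 8.79 and 8.33, UGA4, a GABA permease, at 6.92 and 6.63, DAL4, an allantoin permease, at 5.85 and 7.55, and GAP1, the general amino acid permease, at 3.32 and 3.86. Of 28 list members 23 were at least 2-fold higher with rapamycin and 27 in nitrogen starvation. With rapamycin MEP2, an ammonium permease, was at 5.41, PUT1 of proline breakdown at 5.29 and CHA1, a serine and threonine deaminase, at 6.16. Ribosome biogenesis was as low with rapamycin as in nitrogen starvation (medians −2.73 and −2.72), with UTP21 at −4.28, NOC2 at −4.10 and the polymerase I gene RPA49 at −3.99 on the rapamycin array. The ribosomal protein genes were not alike, at −0.74 [−0.86 to −0.66] with rapamycin and −2.70 [−2.81 to −2.58] in nitrogen starvation, where RPS9A was at −4.76 and RPS9B at −4.62 (a pair whose signals may mix). CIT2, the peroxisomal citrate synthase of the retrograde response, was at 2.40 with rapamycin and −2.63 in nitrogen starvation, and the retrograde list at 1.13 and −0.50.

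The sulfur amino acid genes parted these treatments as well. Their median was −0.76 with rapamycin, 2.91 [2.40 to 3.77] in nitrogen starvation and 3.75 [2.58 to 4.19] in amino acid starvation, where 16 of 19 were at least 2-fold higher, led by MET1 of sirohaem synthesis (6.10) and the S-methylmethionine permease gene MMP1 (5.16). MUP1, a methionine permease, was at −2.88 with rapamycin. Amino acid starvation (588 genes higher, 707 lower) had 20 of 53 amino acid biosynthesis genes at least 2-fold higher around a median of 0.27, among them the serine genes SER3 (3.78) and SER33 (3.08) and HIS4 of histidine synthesis (3.07). Purine synthesis had a median of 1.73, with ADE17 at 4.88 and ADE1 at 3.11, and SNZ1, of vitamin B6 synthesis, stood at 4.58. GCN4, the activator of amino acid synthesis, was at 0.30. Lowest were ZRT1 (−3.53), FUR1, a uracil phosphoribosyltransferase (−3.39), and the copper transporter gene CTR1 (−3.31). FUR1 was also low in nitrogen starvation (−4.43), beside URA7 (−4.64), IMD4 (−4.37) and NOP1 (−4.36).

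In 0.1% glucose (680 genes higher, 851 lower) the glucose-repressed genes had a median of 3.04 [2.33 to 3.66], with 29 of 32 at least 2-fold higher. The glucose transporter genes HXT7 (7.78) and HXT6 (7.63), whose probes may share signal, HXT2 (5.63), the lactate transporter gene JEN1 (5.50), CYB2 of lactate oxidation (5.22), the hexokinase gene HXK1 (5.09) and the invertase gene SUC2 (3.11) stood out, while the low-affinity transporter gene HXT1 was at −4.09. Respiration and TCA cycle genes had a median of 1.38 [1.32 to 1.61], with 39 of 43 at least 2-fold higher, led by SDH4 of succinate dehydrogenase (3.45) and the NADH dehydrogenase gene NDI1 (3.34). Amino acid biosynthesis was lowest here at −0.92, with ARG3 at −3.76 and the aspartate kinase gene HOM3 at −2.53. In KCl (577 higher, 763 lower) the osmotic stress genes had a median of 3.39 [2.15 to 4.32]. TKL2 was at 7.88, ALD3 at 7.81, DDR2 at 7.47, HXT5 at 7.33, SPI1 at 7.25, GRE1 at 6.78, the catalase gene CTT1 at 6.48 and GPD1 of glycerol synthesis at 3.95. The glycerol transporter gene STL1, not measured on every array, reached 9.47. ZRT1 (−4.74), AAH1 (−4.38), UTP20 (−4.36) and RRP12 (−4.32) were lowest, ribosome biogenesis had a median of −2.70 [−3.11 to −2.32] and ergosterol genes one of −0.68.

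Heat shock (742 higher, 848 lower) set apart the heat shock factor targets, chaperones and their partners, with a median of 2.87 [1.95 to 4.23] against −0.94 to 0.77 on the other 6 arrays. HSP30 was at 9.39, the Hsp70 gene SSA4 at 8.25, the small heat shock genes HSP26 at 7.62 and HSP42 at 6.70, BTN2 at 6.94 and HSP82 at 4.19. ATG41, an autophagy gene, was at 7.15, and RPN4, the activator of proteasome genes, at 2.27. NSR1 (−4.73) and ILV5 of branched-chain amino acid synthesis (−3.64) were low, and the haploid pheromone pathway had a median of −1.09, with FAR1, a cell cycle inhibitor, at −3.02. Peroxide (451 higher, 555 lower) gave HSP30 6.10, FIT2, a siderophore-retaining cell wall protein gene, 5.73, DDR2 5.11, HSP26 4.35, the glyceraldehyde phosphate dehydrogenase gene TDH1 4.26 and TIS11, an mRNA decay factor of iron shortage, 4.15. Oxidative defence genes had a median of 0.68, within the 0.53 to 0.88 of the other 6 arrays, though GPX2 (3.38), the peroxiredoxin gene TSA2 (2.58) and the thioredoxin gene TRX2 (1.63) were high and the thioredoxin reductase gene TRR1 was at 0.42. Histone genes were low (median −1.48 [−1.88 to −0.91], HTB2 −2.09, HTA1 −2.00), as was glycolysis (−1.16, with TDH3 at −2.42 and ENO2 at −2.17). No other array had the dye order of the peroxide array, so values particular to it cannot be told apart from dye bias. The proteasome median was 0.68 there and 0.49 in KCl, with PRE1 at 1.16 in peroxide. The cell wall gene CCW12, at −3.01, was above 0 on the other 6 arrays, which had the opposite dye order. Over the 7 arrays the activator gene MSN2 lay between −0.07 and 0.41 and SFP1, an activator of ribosomal genes, between −0.90 and 0.32, HSP12, a general stress gene, ran from 1.69 in amino acid starvation to 4.68 in KCl, and a-specific genes had a median of 0.70 with rapamycin.

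The next comparison set 3 starvations against 3 stresses. Heat shock factor targets were lower in all 3 starvations (list medians −0.94 to 0.30) than in any of the 3 stresses (0.72 to 2.87, highest at heat shock). The intervals of 0.1% glucose (0.30 [−0.34 to 0.81]) and peroxide (0.72 [0.14 to 1.55]) overlapped. With an estimated correlation none of the 13 lists that camera passed at the preset correlation held, the lowest adjusted p being 0.661. The median difference was −1.84 for heat shock factor targets (camera adjusted p = 3.01e-14, 15 genes lower adjusted over the list alone, adjusted p = 0.661 with an estimated correlation).

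For the other lists the difference rested on some of the arrays, and adjusted p with an estimated correlation was 0.661 or above throughout. Sulfur amino acid genes differed by 2.52 (camera adjusted p = 1.34e-10, 6 higher adjusted over the list alone), with 2.91 and 3.75 in nitrogen and amino acid starvation but −0.66 in 0.1% glucose, below heat shock (−0.42) and peroxide (−0.22). Purine synthesis differed by 1.45 (8.14e-03), with 0.59 and 1.73 in nitrogen and amino acid starvation, while 0.1% glucose (−0.56) and peroxide (−0.61) were alike. Nitrogen-repressed genes differed by 1.00 (1.64e-05), with 0.34 in 0.1% glucose, below heat shock (1.11) and peroxide (0.85). Glucose-repressed genes differed by 0.89 (2.69e-05) and respiration by 0.50 (5.65e-06, 1 adjusted over the list alone), where 0.1% glucose stood alone at 3.04 and 1.38. Without it the glucose-repressed medians were 1.10 and 1.27 in starvation against 1.19, 1.28 and 0.25 in stress, and those of respiration 0.24 and 0.18 against 0.33, 0.09 and −0.09. Amino acid biosynthesis differed by 0.34 (9.86e-03) but was lowest in 0.1% glucose, and histones by 0.58 (7.11e-03), with peroxide lowest. Osmotic stress genes differed by −1.43 (1.64e-05, 6 lower adjusted over the list alone) and general stress genes by −0.89 (7.37e-08, 2 lower adjusted over the list alone), though 0.1% glucose (1.40 and 3.06) lay above peroxide (1.29 and 2.25). Ribosomal protein genes differed by −0.86 (2.11e-17), with 0.1% glucose (−1.28) and peroxide (−1.32) alike, translation factors by −0.35 (0.039) and the proteasome by −0.27 (2.25e-03). Ribosome biogenesis did not part the classes (0.05, adjusted p = 0.603).

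Gene by gene, limma gave 0 calls between starvation and stress after adjustment, with 470 genes at an unadjusted p under 0.05, so the 5 genes with the smallest p are given as not past the threshold. JEM1, an endoplasmic reticulum chaperone gene, averaged −2.54 in starvation and −0.19 in stress (adjusted p = 0.255), and ERO1, the oxidase of protein folding in that organelle, −1.81 and 0.95 (0.298). DDR48, a stress protein gene, averaged 0.51 and 2.48 (0.255), the nicotinamidase gene PNC1 1.16 and 3.04 (0.298) and HSP26 0.03 and 5.51 (0.298). Without the glucose array 48 genes passed, and in the 4 arrays with filled zeros 51. On simulated data 4% of genes changed by 1 and 54% of those changed by 2 were recovered in this design, against 78% and 96% for the common response.

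Nitrogen starvation combined with KCl showed marks of both (903 genes higher, 1021 lower). The 3 combined arrays kept dim spots, as did 0.1% glucose, while nitrogen starvation, KCl and rapamycin alone had filled zeros. Treatment and spot handling therefore cannot be told apart where a combined array is compared with nitrogen starvation, KCl or rapamycin alone. Compared with nitrogen starvation alone, osmotic stress genes were higher by a median of 1.69 [1.42 to 3.04] and general stress genes by 1.48 [1.06 to 1.91], with 29 of 45 at least 2-fold higher. ALD3 was higher by 6.12, TKL2 by 5.32, GRE1 by 5.22, CTT1 by 4.63 and HXT5 by 4.57. Ribosomal protein genes were lower still, with a median difference of −1.01 [−1.18 to −0.86] and 70 of 135 at least 2-fold lower, to a median of −3.94 on the combined array, and ribosome biogenesis differed by −0.72 to reach −3.42 [−3.96 to −2.96]. Purine synthesis (−1.14), amino acid biosynthesis (−1.01), glycolysis (−0.80) and sulfur amino acid genes (−0.74) were lower, as were the permease gene SEO1 (−4.21) and the elongation factor gene YEF3 (−3.24). The combined array had a wider spread across genes than nitrogen starvation alone (SD 1.57 against 1.22). Scaling arrays to 1 spread left 71 genes higher and 213 lower in this difference, from 202 and 465.

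Compared with KCl alone, the nitrogen genes set the combined array apart. Nitrogen-repressed genes were higher by a median of 2.37 and sulfur amino acid genes by 3.22 [1.43 to 4.11], with 17 of 19 at least 2-fold higher. MEP2 was higher by 6.98, DAL5 by 6.88, MMP1 by 6.62 and the arginase gene CAR1 by 5.57. Ribosomal protein genes were lower, at −2.92 [−3.11 to −2.63] with 126 of 135 at least 2-fold lower (RPL22A −4.75), and so was glycolysis (−2.39, TDH2 −4.91). General stress genes differed by −0.31 and osmotic stress genes by −0.36. Scaling arrays to 1 spread left 173 genes higher and 303 lower in the difference from KCl, from 323 and 500. Set against the sum of both single treatments, ribosome biogenesis was less low than the sum by 1.82 [1.67 to 1.93], with NOP7 at 3.45 and DRS1 at 3.42, and 59 of 64 genes were at least 2-fold above it. Polymerase genes were above it by 1.47. General stress genes were below the sum by a median of −1.72 [−2.03 to −1.56], with DDR2 at −5.41 and SPI1 at −4.37, as were glycolysis (−1.70), osmotic stress (−1.20) and glucose-repressed genes (−1.17). Ribosomal protein genes went both ways around the sum, 13 at least 2-fold above it and 24 below (median −0.12 [−0.34 to 0.02]), as did sulfur amino acid genes (3 above and 5 below of 19, median 0.05).

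Removing glucose together with nitrogen gave a pattern unlike nitrogen starvation alone (619 genes higher and 885 lower, or 549 lower with the array centred on its median of −0.22). The combined array kept dim spots, while the nitrogen starvation array had filled zeros. Nitrogen-repressed genes were lower than in nitrogen starvation by a median of −2.09 and sulfur amino acid genes by −3.05 [−3.60 to −1.92], with 18 of 19 at least 2-fold lower. SEO1 differed by −7.42, DAL5 by −6.70, DAL4 by −5.86, the urea permease gene DUR3 by −5.85, MET5 by −4.71 and MET1 by −4.70. Ribosomal protein genes were less low, differing by 1.79 [1.68 to 1.92] with 115 of 135 at least 2-fold higher, and so was ribosome biogenesis (1.32 [1.10 to 1.60], 46 of 64). Glucose-repressed genes were higher by 1.54 [1.16 to 2.18], with HXT2 at 6.36, HXT6 at 5.38 and JEN1 at 5.24, and glycolysis by 1.60, CIT2 by 4.03. Purine synthesis (−1.62) and amino acid biosynthesis (−0.76) were lower.

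Adding glucose starvation to rapamycin (550 genes higher and 698 lower, or 455 lower with the array centred on its median of −0.19) gave a like picture, and both combined arrays correlated across genes at 0.901. Both combined arrays kept dim spots, while the rapamycin array had filled zeros. Nitrogen-repressed genes were lower than with rapamycin alone by a median of −2.32, with DAL5 at −7.42, CHA1 at −6.50, UGA4 at −5.52, DAL7 at −4.94 and MEP2 at −4.65. Ribosome biogenesis was less low by 1.63 [1.35 to 1.75], with 52 of 64 genes at least 2-fold higher, while ribosomal protein genes differed by −0.16 [−0.26 to 0.03]. Glucose-repressed genes were higher by 1.12, with JEN1 at 5.82, HXT6 at 5.27 and HXT2 at 4.25, ZRT1 was higher by 4.94, and general stress and sulfur amino acid genes were each higher by 0.59.

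Against 0.1% glucose alone, both combined arrays had higher growth genes and lower general stress and respiration genes, though they also differ in the glucose left, since the combined starvations removed it. The median difference of ribosome biogenesis was 0.99 with nitrogen starvation and 1.16 with rapamycin, that of ribosomal proteins 0.30 and 0.48, that of general stress genes −1.05 and −1.04 and that of respiration −1.04 and −1.14. Heat shock factor targets were not lower, at 0.24 [−0.03 to 0.72] and 0.26 [−0.04 to 0.56], with HSP30 higher by 2.75 and 3.08. ATG41 was higher by 5.79 and 5.64, ZRT1 by 4.01 and 4.97 and HXT1 by 3.38 and 4.56. With nitrogen starvation ARG3 (3.03) and URA7 (2.98) were also higher, and ARO9, an aromatic aminotransferase gene (−2.79), and HXT7 (−1.98) lower, while osmotic stress genes differed by −1.08, sulfur amino acid genes by 0.68 and glucose-repressed genes by 0.04. With rapamycin amino acid biosynthesis differed by 0.64 and glucose-repressed genes by −0.43, and MAL33 and the cytochrome gene CYC7 were both at −2.52.

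**Figure D2:**
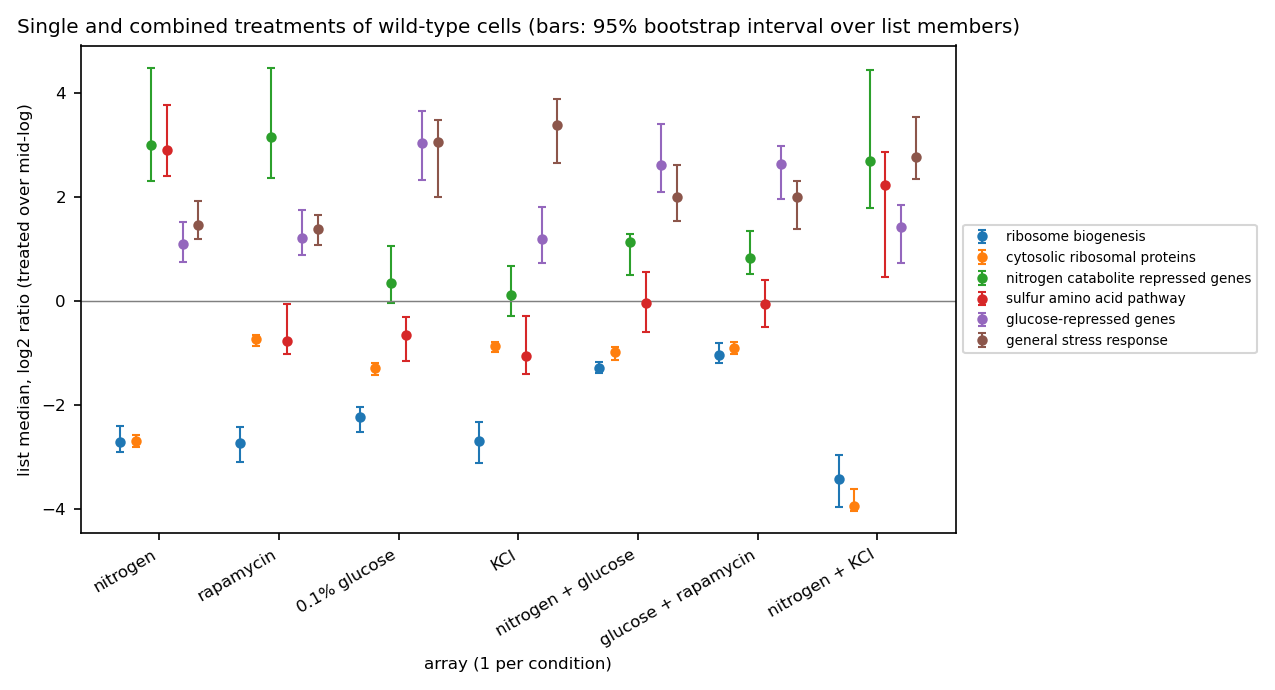
Median log2 ratio over mid-log cells (vertical axis, log2) of gene lists for combined and single treatments of wild-type cells, with 95% bootstrap intervals over list members as bars. Nitrogen-repressed genes stood at 3.01 in nitrogen starvation, 1.14 once glucose was also removed and 2.69 with KCl.

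In mid-log growth snf1 cells differed from wild-type cells at few genes (93 at least 2-fold higher, 72 lower). Glucose transporter genes were lowest, HXT7 at −3.49, HXT6 at −3.44 (a pair that may share signal), HXT4 at −3.44 and HXT2 at −2.51, followed by ADH4 at −2.06, ZPS1 at −1.63, PGM2, a phosphoglucomutase gene, at −1.44 and MBR1 at −1.37. The glucose-repressed list had a median of −0.49 [−0.85 to −0.36], with 8 of 32 at least 2-fold lower, though the isocitrate lyase gene ICL1 was at 1.88. FIT2 (3.69), FIT3 (3.53) and the siderophore transporter gene ARN2 (2.92) were highest. TFB3 (2.43), SAS10 (2.15), RAD28 (2.12), HMLALPHA2 (2.06) and MATALPHA1 (2.04) followed, the alpha genes being near-identical copies. High genes of this array were also above 0 on the 6 wild-type arrays of the same dye order, with medians of 0.39 to 0.93, and not on the turned peroxide array, with a median of −0.16. Glycolysis (0.63, TDH3 1.69) and ribosomal proteins (0.52 [0.44 to 0.56], 7 of 135 at least 2-fold higher) were higher, and general stress genes were lower (−0.23 [−0.40 to −0.03]), with SDH2 of respiration at −1.29.

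The last comparison asked how the responses to nitrogen starvation, KCl and 0.1% glucose differed in snf1 cells. In nitrogen starvation and KCl the wild-type arrays had filled zeros and the snf1 arrays kept dim spots. Strain and spot handling therefore cannot be told apart there, while in 0.1% glucose both arrays kept dim spots. General stress genes were lower in the snf1 response to each treatment (median differences of −0.64, −0.67 and −0.70 in that order), as were glucose-repressed genes (−0.62, −0.31 and −1.58). Ribosomal protein genes were higher in KCl (0.55) and 0.1% glucose (0.95), and in nitrogen starvation they did not stand out from other genes (0.08, against 0.04 for all genes). By camera over the 3 treatments, with an estimated correlation, adjusted p was 0.21 for general stress genes and 0.782 for glucose-repressed and ribosomal protein genes. Ribosome biogenesis and amino acid genes were higher in KCl (0.41 and 0.21) and 0.1% glucose but not in nitrogen starvation (−0.21 and −0.08), and respiration was lower in nitrogen starvation (−0.24) and 0.1% glucose but not in KCl (−0.01). At 0.1% glucose glucose-repressed genes were lower by a median of −1.58 [−2.19 to −0.97], with 21 of 32 at least 2-fold lower. HXT2 differed by −4.73, HXT7 by −4.30, HXT6 by −4.05, JEN1 by −3.93, ARO9 by −3.71, IDP2, an isocitrate dehydrogenase gene, by −3.32 and CAT8, an activator of gluconeogenesis, by −2.85. Respiration was lower by −0.87 [−1.02 to −0.69]. Ribosome biogenesis was higher by 1.06 [0.97 to 1.23], ribosomal proteins by 0.95 [0.87 to 0.99] and amino acid biosynthesis by 0.90 [0.82 to 1.04], with HOM3 at 3.18, HIS1 at 2.69 and ARG4 at 2.54. Blank spots stood at 2.30 on that snf1 array and −0.77 on the wild-type one, so background could raise these lists. On the snf1 0.02% glucose array, blank spots stood at −0.66. There ribosome biogenesis lay above wild-type cells in 0.1% glucose by 1.79 [1.64 to 2.03] and ribosomal proteins by 0.90 [0.83 to 0.95]. That comparison differs in glucose level as well. The polyamine transporter gene TPO2 (4.21), HSP30 (4.19), ATG41 (3.41), CHA1 (2.99), GPP1 of glycerol synthesis (2.83) and ZRT1 (2.69) were also higher, and G1/S genes had a median of −1.77 in snf1 cells against −1.33 in the wild type.

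In nitrogen starvation the genes lowest in the snf1 response were FIT3 (−4.50), FIT2 (−4.12), ARN2 (−3.70), TKL2 (−3.46), SPI1 (−3.40), HSP30 (−3.21) and SIT1 (−3.18), of which FIT3, FIT2 and ARN2 were high in mid-log snf1 cells, with list medians of −1.07 for glycolysis, −0.81 for purine synthesis and −0.57 for osmotic stress. In KCl PUT1 (−2.66), SIT1 (−2.54), GRE1 (−2.52) and HXT5 (−2.32) were lower in snf1 cells and GAP1 (2.08) and CHA1 (1.96) higher. Adding the mid-log difference gives treated snf1 over treated wild-type cells, in which the glucose-repressed median was −1.08 in nitrogen starvation, −0.81 in KCl and −1.96 [−2.96 to −1.30] in 0.1% glucose. There HXT7 was at −7.79, HXT6 at −7.49, HXT2 at −7.24, HXT4 at −6.04, JEN1 at −4.93, SUC2 at −3.65 and ADR1, an activator of glucose-repressed genes, at −3.38, and HSP30 at 5.88. Responses of both strains correlated across genes at 0.916 in nitrogen starvation, 0.923 in KCl and 0.789 in 0.1% glucose.

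Over the 3 treatments limma gave 0 calls between the strains after adjustment, with 626 genes at an unadjusted p under 0.05. The 5 genes with the smallest p, each at an adjusted p of 0.0886 and lower in snf1 cells in 3 of 3 treatments, were DDR2 (a mean response of 3.94 in snf1 and 6.15 in wild-type cells), SPI1 (2.19 and 4.79), HBT1 (1.58 and 3.56), the siderophore transporter gene SIT1 (−2.60 and −0.08) and GND2, a 6-phosphogluconate dehydrogenase gene (1.76 and 3.75). Without nitrogen starvation 44 genes passed, and in simulation 37% of genes changed by 1 and 73% of those changed by 2 were recovered. By camera ribosomal proteins (median 0.51, adjusted p = 2.45e-23), ribosome biogenesis (0.40, 2.06e-06), amino acid biosynthesis (0.32, 6.93e-06), translation factors (0.29, 1.09e-03), histones (0.34, 0.011, 1 adjusted over the list alone) and polymerases (0.33, 0.0424) were higher in the snf1 response. General stress (−0.60, 1.74e-18, 17 lower adjusted over the list alone), glucose-repressed genes (−0.84, 4.97e-11, 6 lower adjusted over the list alone), respiration (−0.36, 8.94e-08), osmotic stress (−0.24, 8.9e-03), glycolysis (−0.37, 0.0105), oxidative defence (−0.16, 0.0105) and heat shock factor targets (−0.09, 0.0406, 3 lower adjusted over the list alone) were lower. With an estimated correlation no list passed, at adjusted p = 0.21 for general stress and 0.782 or above for the other lists named. With members found in 1 list only, camera no longer passed osmotic stress (adjusted p = 0.299), heat shock factor targets (0.43) and polymerases (0.0501). In nitrogen starvation the medians of ribosome biogenesis, amino acid biosynthesis, translation factors and polymerases had the other sign, as had those of glycolysis and heat shock factor targets in 0.1% glucose.

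In snf1 cells a lower glucose level, 0.02% against 0.1%, went with fewer changed genes (297 higher and 281 lower against 477 and 660). Blank spots stood at −0.66 on the 0.02% array and 2.30 on the 0.1% array. Differences in glucose level and in background therefore cannot be told apart here, and the cause was not tested. General stress genes were lower at 0.02% by a median of −0.86, with ALD3 at −2.88, the glycogen phosphorylase gene GPH1 at −2.85, PGM2 at −2.38 and CTT1 at −2.23, and osmotic stress genes by −0.75. Ribosome biogenesis was higher by 0.68, with SDA1 at 2.06, and so were BTN2 (4.22), CIT2 (2.91) and RNR1 (2.01). Glucose-repressed genes differed by −0.52, respiration by −0.38 and ribosomal proteins by −0.03.

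**Figure D3:**
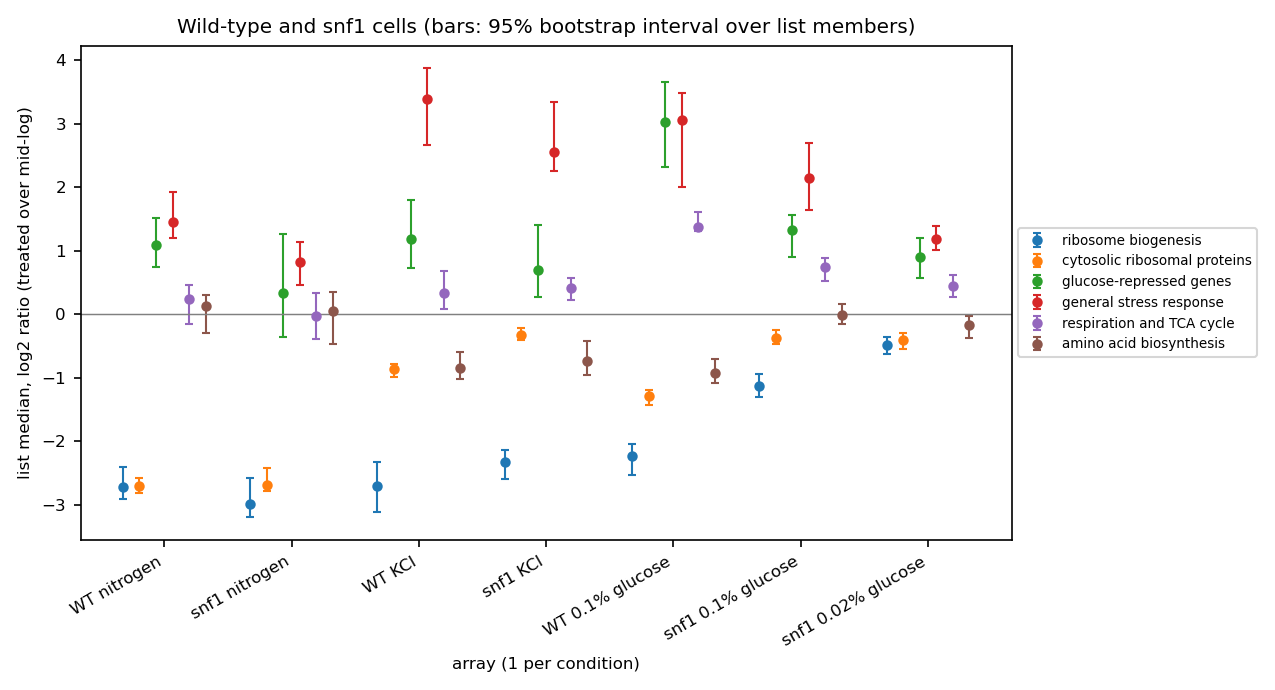
Median log2 ratio over mid-log cells (vertical axis, log2) of gene lists in wild-type and snf1 cells for each shared treatment, with 95% bootstrap intervals over list members as bars. Glucose-repressed genes stood at 3.04 in wild-type and 1.33 in snf1 cells in 0.1% glucose.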

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

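All tests of explanations in this part were chosen after the results were seen.

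The common response of the 7 wild-type arrays, with ribosome biogenesis genes lower and general stress genes higher, was weighed first. Only 1 of 64 sign patterns, the real one, called as many genes (2377, with 23 as the highest of the others). Pairs of the 7 arrays correlated at 0.501 to 0.885, so turning any array cancels what they share. The sign patterns also treat the arrays as independent, so this count by itself cannot exclude chance or a shared control. Gene-specific dye bias is excluded as the whole cause, because 85.4% (1991 of 2332, 95% Wilson interval 83.9 to 86.8) of the genes called from the 6 arrays of one dye order lay on the same side of 0 on the turned peroxide array, where bias would reverse them. The Wilson intervals here count genes as independent, which they are not, so they are too narrow. Noise of a shared wild-type mid-log pool is excluded as the whole cause by the 4 snf1 treatment arrays, whose control was mid-log snf1 RNA. On each of them 86.8% (2064 of 2377, Wilson interval 85.4 to 88.1) or more of the called genes lay on the called side of 0. The highest covariance of the strain array with any of the 7 was 0.009, against 0.460 to 1.184 among the 7. That covariance bears on the question only if the strain array used the same pool, which the labels do not say. Handling of cells common to all treatments stays open, so a shared growth and stress response remains a hypothesis.

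The lower glucose-repressed genes in the snf1 response to 0.1% glucose, such as HXT2 and JEN1, were weighed next. Blank spots of that array had a ratio of 2.30 (1.03 to 3.22) against −0.77 (−1.67 to 1.38) on the wild-type array, a difference of 3.07. Background pulls ratios towards that of the blank spots, so it would raise snf1 ratios below 2.30 but lower those above it. It is therefore not excluded as a part of the cause. On the snf1 0.02% glucose array, with blank spots at −0.66, the list also lay below wild-type cells in 0.1% glucose, by −2.16 [−3.06 to −1.28]. That comparison differs in glucose level as well. A mid-log difference between the strains would need the list to be higher in mid-log snf1 cells, and is excluded by a median of −0.49 [−0.85 to −0.36] there. Differences between cultures stay open with 1 array each, so a weaker induction without Snf1 is a hypothesis.

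The genes higher in mid-log snf1 cells, among them TFB3, RAD28 and 4 alpha genes, were weighed last. Gene-specific dye bias is a candidate explanation for many of them, since the 93 genes had medians of 0.39 to 0.93 on the 6 wild-type arrays of the same dye order and −0.16 [−0.39 to −0.03] on the turned peroxide array, with 74 above 0 in the mean of the 6 arrays and 35 above 0 in peroxide. A rise of the general stress genes in mid-log snf1 cells was not seen, with a median of −0.23 [−0.40 to −0.03]. Another stress-like state is not excluded, since that list alone cannot test it. A mating-type difference is not needed to explain the alpha genes, which were at 1.27 to 2.06 on the strain array. Their median was 0.85 to 2.17 on the 9 wild-type arrays of that dye order, and their values in peroxide were −0.23 to −0.07. A mating-type difference is not excluded as a part of the cause. Of the 93 genes 47 were also called higher in the common response, and the 72 genes lower in snf1 cells had medians of −0.07 to 0.47 on the 6 arrays and 0.10 in peroxide. Whether FIT2, FIT3 and ARN2, which were high in peroxide too, differ between the strains stays open.

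The difference between the strains was picked out because camera tested it directly and passed it for 13 lists, though for 0 with an estimated correlation. The snf1 minus wild-type medians were 0.51 for ribosomal proteins, 0.40 for ribosome biogenesis, 0.33 for RNA polymerases I and III, 0.29 for translation factors, 0.32 for amino acid biosynthesis and 0.34 for histones. They were −0.84 for glucose-repressed genes, −0.60 for general stress, −0.36 for respiration, −0.37 for glycolysis, −0.24 for osmotic stress, −0.16 for oxidative defence and −0.09 for heat shock factor targets. The real count in limma was 0 genes, which every split must reach, so the 10 splits of these 6 arrays could not test it (highest other 9). They are also too few for a share under 0.05. The 4 splits that part all 3 treatment pairs, the real one among them, each gave 0. For starvation against stress the real count was likewise 0, so the 10 splits (highest other 2) could not test it and are too few for a share under 0.05.

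Blank control spots, which lie outside the gene measurements, kept a ratio on the 8 arrays without filled zeros or blanks, and their median was at least 2-fold from 0 on 4 of them. It was −1.34 in snf1 nitrogen starvation, 2.30 in snf1 cells at 0.1% glucose, −1.39 in nitrogen and glucose starvation and −1.86 in nitrogen starvation with KCl. On the other 4 it was −0.77 in wild-type cells at 0.1% glucose, −0.66 in snf1 cells at 0.02% glucose, −0.67 in glucose starvation with rapamycin and 0.45 in snf1 cells in KCl.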

How the results depend on the processing

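Zeros kept as values, the arrays with filled zeros alone and all list members with a value were tried after seeing the data. The common response called 2377 genes. It called 2010 to 2776 in all alternatives other than the peroxide array as deposited and leaving arrays out, 1990 to 2400 with each array left out, 1207 higher and 1157 lower on centred arrays, 1188 and 1451 with zeros kept and 878 and 1132 in 5 arrays with filled zeros. With the peroxide array as deposited it called 18 higher and 5 lower, 23 in all, which follows from opposing that array to the rest, and 20 named genes lost their call. Starvation against stress ran from 0 to 48 genes with 1 array left out (48 without the wild-type glucose array, 0 for each other) and reached 51 in the 4 arrays with filled zeros. The cause was not tested. The strain comparison ran from 0 to 44 with 1 treatment left out (44 without nitrogen starvation) and gave 1 after scaling to a common spread. The cause was not tested. Lists past camera went from 13 to 0 with an estimated correlation in each of the 3 models, 0, 0 and 0, and stood at 13, 13 and 10 with members of 1 list only, which ended osmotic stress, heat shock factor targets and polymerases in the strain comparison. With all genes with a value, more genes were counted, with 766 higher in snf1 KCl (from 496), 471 higher and 470 lower in snf1 0.02% glucose (from 297 and 281), 1076 higher in snf1 0.1% glucose (from 477) and 1021 higher in nitrogen and glucose starvation (from 619). Centring, which removes the shift of the array, left 549 lower in nitrogen and glucose starvation (from 885), 455 lower in glucose starvation with rapamycin (from 698) and 11 higher for snf1 minus wild type in nitrogen starvation (from 17). Scaling to a common spread shrinks the nitrogen with KCl array and stretches the mid-log strain array (SD 1.57 and 0.456). It lowered the counts to 71 higher and 213 lower for nitrogen with KCl minus nitrogen (from 202 and 465) and to 173 and 303 for it minus KCl (from 323 and 500). It lowered them to 234 lower for nitrogen and glucose starvation minus 0.1% glucose (from 392), and to 6, 29 and 225 higher for snf1 minus wild type in nitrogen starvation, KCl and glucose (from 17, 53 and 362). For treated snf1 over treated wild type it raised them to 705 and 903 in nitrogen starvation (from 307 and 486), 752 and 788 in KCl (from 304 and 353) and 984 lower in glucose (from 598). Of 696 list medians, 696 stayed within their bootstrap interval with all members, while centring moved 31 out of it and reversed 3. With another probe choice 696 stayed within it too, but only 7 genes had several probes, so that choice could hardly move a median. Mitochondrial ribosomal proteins turned from −0.19 to 0.03 and the proteasome from −0.15 to 0.07 in nitrogen and glucose starvation, and the proteasome from −0.18 to 0.01 in glucose starvation with rapamycin. Signal over background is unknown, since only ratios were used, and dim genes on the 8 arrays that kept them may carry the ratio of the blank spots, up to 2.30.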

Other observations

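Several siderophore and iron genes were picked for this part after their values were seen, and as a group they were not tested. FIT2 stood at 5.73 in peroxide and 3.69 in mid-log snf1 over wild-type cells, and at −3.79 in snf1 nitrogen starvation. The siderophore transporter genes ARN1 and ARN2 were at 2.42 and 3.76 in peroxide, 1.37 and 2.92 in mid-log snf1 cells and −3.19 and −2.81 in snf1 nitrogen starvation, and SIT1 went from 3.28 in peroxide to −3.77 in snf1 0.1% glucose. TIS11 was at 4.15 in peroxide, −2.67 in wild-type 0.1% glucose and −3.10 in snf1 nitrogen starvation, and the iron reductase gene FRE1 at −3.69 in snf1 KCl. The zinc transporter gene ZRT1 lay between −4.74 and −3.53 with rapamycin, in the 3 starvations and in KCl, but at −0.33 at heat shock and −0.58 in peroxide, and at −0.34 and 0.62 where glucose was removed together with nitrogen or with rapamycin. ZAP1, the zinc-responsive activator, was at −3.83 in 0.1% glucose and −0.09 at heat shock. The copper metallothionein genes CUP1-1 and CUP1-2, which may share signal, were at 5.42 and 5.53 in nitrogen starvation and 6.26 and 6.35 in snf1 nitrogen starvation, while the copper transporter gene CTR1 was at −3.05 and −3.17.

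The following genes were also chosen after their values were seen. The permease gene SEO1 was at 7.80 in nitrogen and 7.56 in amino acid starvation and 0.59 with rapamycin, and at 0.38 where glucose was removed as well. CHA1 was at 6.16 with rapamycin and 0.36 in nitrogen starvation. HSP30 was at 3.64 in wild-type 0.1% glucose, 7.83 in snf1 0.1% glucose, 6.71 in snf1 0.02% glucose, 6.39 in nitrogen and glucose starvation and 6.72 in glucose starvation with rapamycin. The mitotic cyclin gene CLB2 was at −3.08 and −2.79 in those 2 combined starvations and −0.47 in nitrogen starvation. In snf1 0.1% glucose CLN2 was at −3.55, RNR1 at −3.36 and CLN1 at −2.91. The cell wall gene CWP2 was at −2.57 in peroxide and above 0 on the other 6 wild-type arrays of single treatments, as CCW12 was.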
